A study of Mus musculus with 6 samples.

How the data were processed

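Small intestine tumors were profiled from mice whose floxed Prkci and Prkcz genes, which encode the atypical protein kinase C isoforms, were targeted by Villin-Cre, a recombinase expressed in intestinal epithelium. Per the labels' protocols, mice aged 11 weeks received vehicle or PEGPH20, a pegylated recombinant human hyaluronidase, at 0.0375 mg/kg for 3 weeks with 2 doses per week, and the tumors were taken at 14 weeks of age. Total RNA (200 ng) was made into 3' mRNA libraries with the QuantSeq forward kit and optional molecular identifiers, which were read from a single end over 75 nt on an Illumina NextSeq instrument. The kit counts tags near the 3' end of a transcript and keeps strand.

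The authors deposited a table of 21878 gene rows and 6 library columns, with genome build GRCm38 named in the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of the molecular identifiers are not given in the sources used here. The deposited values are a signal in CPM: gene counts divided by the library total and scaled to 1000000, read from the values themselves since the gene rows of each column sum to 1000000. A further row named as the total holds 1000000 in every column, names no gene and was left out. Because each value is a whole multiple of what 1 read is worth, reads were recovered by division. With a tolerance of 1e-06 of a read, 100% of the values came out whole, and the recovered totals ran from 2075588 to 2832876 reads. One read was worth 0.353 to 0.482 CPM. Gene identifiers were matched to GENCODE release M21 on GRCm38 for symbols and positions, which was possible for 21786 identifiers and not for 92.

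Libraries were assigned to groups by the treatment label, with 3 libraries per group. The labels share no replicate number between groups, so no pairing was modelled. They do not state that each tumor came from a separate mouse, so p-values measure the spread between these samples. No libraries were duplicates: over 11224 genes with at least 60 reads summed over all libraries, chi-square per degree of freedom ran from 2.42 to 35.8 in the 15 pairs.

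The planned test was edgeR's quasi-likelihood test for counts, with limma as the written choice should the values be normalized. They were, so limma 3.58.1 with a mean-variance trend was fitted to log2(value + 1) of all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are PEGPH20 minus vehicle on the log2(CPM + 1) scale, which understates the change of genes with low values. Genes were kept by filterByExpr with its defaults on the recovered reads (minimum count 10), leaving 11389. Intervals on counting were not used, since the use of molecular identifiers is not known. A count of 0 allows up to 3 reads, which is 1.06 to 1.45 CPM across libraries.

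Before the data were examined, 38 gene lists were fixed for hyaluronan, matrix, stroma, immune, epithelial and stress programs and for markers of other cell types. Each was tested with camera at a preset correlation of 0.01 on log2(CPM + 1), then with an estimated correlation, and with fry, adjusting over the 38 lists. The design named log2 CPM with a prior count of 2 for this step, which was run as an alternative. A list level is the mean log2(CPM + 1) of its measured genes in a library minus the vehicle mean. Lists share genes: 6 measured genes are in both the fibrillar matrix and the fibroblast list.

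Named genes followed a rule fixed beforehand. As fewer than 10 genes passed, it took the 10 smallest p-values in each direction among annotated genes whose groups did not overlap and whose mean log2(CPM + 1) was at least 1. It added the 3 members with the smallest p-values of each described list, and Prkci, Prkcz, Has1, Has2, Has3 and Cd44. Genes named outside this rule are said to be chosen after their values were seen.

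On simulated reads for the 11389 genes with 200 changed (5 simulations), limma recovered 25.8% of genes with a 2-fold change and 85.8% with a 4-fold change, and 6.33% of its calls were false. A 2-fold lowered matrix list was called in 5 of 5 simulations, with the preset and with the estimated correlation. Of the 35 lists that share no gene with it, the preset correlation gave 4 calls over the 5 simulations. Genes were drawn independently there, so the simulation does not show how camera behaves with correlated genes. Alternatives planned before the data were examined were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, other filters, pseudocounts of 0.1 and 5, leaving out each library, and for lists fry, cameraPR and a prior count of 0.5. Alternatives added after seeing the data were edgeR 4.0.16 on the recovered reads with and without PEGPH20 replicate 5, TMM scaling, array weights, an estimated correlation without that library, and for lists the pseudocounts and the prior count of 2. The software was R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.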

Results

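Gene expression was measured by 3' mRNA sequencing in 6 small intestine tumors of mice with intestinal loss of both atypical protein kinase C genes, 3 treated with vehicle (replicates 1 to 3) and 3 with PEGPH20 (replicates 4 to 6). PEGPH20 degrades hyaluronan, a glycosaminoglycan of the extracellular matrix. The comparison asks which transcripts differ in these tumors after treatment. Vehicle libraries held 2075588, 2615578 and 2616142 reads and PEGPH20 libraries 2832876, 2399484 and 2197222. Between 16826 and 17838 genes were detected per library. The 20 most abundant genes took 30.5% to 36.3% of reads, with mitochondrial ribosomal RNA at 12.6% to 16.4%.

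PEGPH20 replicate 5 stood apart from the rest. Its correlation with the other libraries across genes was 0.836 to 0.901, against 0.945 to 0.979 among the other 5. The first principal component held 65.0% of the variance and placed it at 78.9, with the other libraries between -31.6 and 4.42. It also had the largest share of mitochondrially encoded mRNA, 5.15% against 3.34% to 3.99% in the others.

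**Figure D1:**
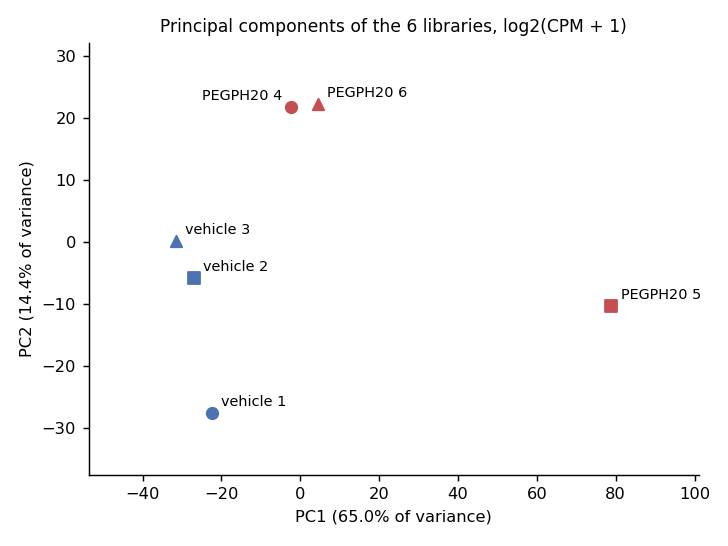
Principal components of log2(CPM + 1) in the 6 libraries, with PC1 (65.0% of the variance) on the horizontal axis and PC2 (14.4%) on the vertical axis; points are libraries and colours are groups. PEGPH20 replicate 5 lies at 78.9 on PC1 and the vehicle libraries between -31.6 and -22.4.

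The targeted genes gave no check of genotype, since both groups carry the same one and 3' tags can lie outside a deleted part. Prkci was at 23.4 ± 6.59 CPM in vehicle and 27.7 ± 8.10 CPM in PEGPH20 tumors (SD, n = 3 each), and Prkcz at 5.06 ± 3.14 and 11.3 ± 4.85 CPM. Neither passed the limma test (adjusted p = 0.664 and 0.248). Of the hyaluronan synthases, Has2 had 19 reads in all vehicle and 14 in all PEGPH20 libraries, Has3 had 2 and 2, and Has1 had 0 and 1, too few to test. Cd44, a hyaluronan receptor, was at 272 ± 68.6 and 184 ± 101 CPM (log2 difference -0.73, adjusted p = 0.406), with 273, 74.6 and 204 CPM in PEGPH20 replicates 4, 5 and 6 and a difference of -0.18 without replicate 5 (0.690).

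In PEGPH20 tumors 3 genes rose and 6 fell, of 11389 tested. Ubb, which encodes polyubiquitin, rose from 2.65 ± 1.70 to 226 ± 28.8 CPM (SD, n = 3 each; log2 difference 6.05, SE 0.31, adjusted p = 0.000916). Clca3b, a member of the calcium-activated chloride channel regulator family, rose from 76.0 ± 4.50 to 183 ± 20.3 CPM, and the mitochondrial alanine tRNA mt-Ta from 8.54 ± 2.24 to 44.5 ± 6.29 CPM. Genes that fell included Cirbp, a cold-inducible RNA-binding protein (57.0 ± 8.25 to 17.1 ± 1.08 CPM, log2 difference -1.67) and Fkbp5, a glucocorticoid-responsive co-chaperone (46.4 ± 6.07 to 11.7 ± 2.09 CPM, -1.90). Ndrg1, a gene induced by hypoxia, fell too (230 ± 6.19 to 98.7 ± 10.8 CPM, -1.21). The other falls were in Fmo2, a flavin monooxygenase (50.4 ± 10.1 to 9.53 ± 3.35 CPM, -2.31), and in Wif1, a secreted Wnt inhibitor (26.1 ± 2.47 to 2.40 ± 1.36 CPM, -3.09). Pi15 fell from 21.8 ± 2.99 to 1.54 ± 1.21 CPM (-3.28). Adjusted p was 0.0361 for Clca3b, mt-Ta, Cirbp, Fkbp5 and Ndrg1 and 0.0378 for Fmo2, Wif1 and Pi15. In each of the 9 genes all 3 PEGPH20 libraries lay beyond all 3 vehicle libraries.

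On GRCm38 these genes lie on separate parts of the genome. Ubb (ENSMUSG00000019505) spans chromosome 11 from 62551171 to 62553213 and Cirbp (ENSMUSG00000045193) chromosome 10 from 80165985 to 80172786. Fkbp5 (ENSMUSG00000024222) spans chromosome 17 from 28399094 to 28517527 and Ndrg1 (ENSMUSG00000005125) chromosome 15 from 66929318 to 66969640. Wif1 (ENSMUSG00000020218) is on chromosome 10 from 121033960 to 121100650, and Fmo2 and Pi15 are both on chromosome 1. The values of Ubb, Clca3b and mt-Ta are uncertain to the extent that reads were split with near-identical copies. Clca3b has these in its gene family and mt-Ta in nuclear copies of mitochondrial DNA.

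**Figure D2:**
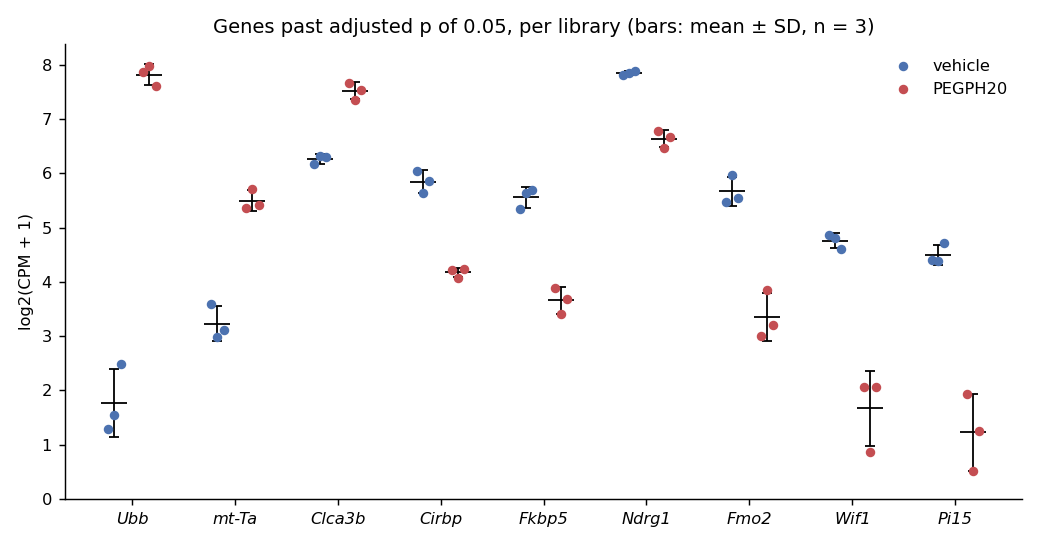
Expression of the 9 genes past the threshold as log2(CPM + 1) on the vertical axis, per gene on the horizontal axis; points are libraries, and bars show mean ± SD (n = 3 per group). Ubb sits at 1.45 to 4.59 CPM in vehicle and 194 to 250 CPM in PEGPH20 libraries.

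The next genes by p-value did not pass the threshold, with adjusted p from 0.0722 to 0.0841. On the higher side they were the chaperones Hsph1 (20.99 ± 2.63 against 77.0 ± 22.7 CPM, SD, n = 3 each) and Hsp90b1 (381 ± 12.8 against 657 ± 58.9 CPM) and the brush border protease Mep1b (154 ± 14.4 against 491 ± 192 CPM). Ifit1bl2, Mbl2, mt-Ti and mt-Tm were the others. On the lower side they were the transferrin receptor Tfrc (374 ± 19.9 against 175 ± 25.6 CPM) and the neutrophil collagenase Mmp8 (22.5 ± 2.16 against 1.89 ± 1.79 CPM). They also included the mitophagy gene Bnip3 (64.7 ± 5.61 against 24.6 ± 5.61 CPM) and Bmyc. At an unadjusted p under 0.05 there were 2050 genes, 743 higher and 1307 lower, where 569 would be given by chance. Groups did not overlap in 27.3% of genes, against 10% by chance. Both chance values are averages. Genes vary together across these libraries, and the spread around the averages was not assessed, so an excess over chance is not shown.

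The count of genes past the threshold depended on single libraries. Without PEGPH20 replicate 5 it was 339 (108 higher, 231 lower), which included all 9 genes above. Leaving out any other library gave 1 to 4 genes, with Ubb past the threshold each time. Without replicate 5, 43 further named genes passed, such as Hsph1 (log2 difference 2.06, adjusted p = 0.000369), Tfrc (-1.07, 0.00294) and Col3a1 (-0.99, 0.000790).

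Genes of fibrillar collagen and matrix were lower in PEGPH20 tumors. Of 31 measured members 30 were lower, with a median log2 difference of -1.18. Of these 22 passed when adjusted over the list alone, against 0 over all genes tested. Col3a1, a fibrillar collagen, was at 543 ± 13.8 CPM in vehicle and 224 ± 83.9 CPM in PEGPH20 tumors (SD, n = 3 each). Eln, which encodes elastin, was at 37.8 ± 4.59 and 16.4 ± 4.95 CPM, and Col6a1 at 49.3 ± 3.93 and 24.6 ± 6.23 CPM. The basement membrane list had all 14 members lower (median -1.13), and 8 passed when adjusted over the list alone, with 0 over all genes. Its leading members were Col4a2 (167 ± 10.9 against 60.2 ± 33.2 CPM), Col4a1 (253 ± 9.40 against 104 ± 56.8 CPM) and the laminin gene Lamb1 (197 ± 19.6 against 84.4 ± 38.2 CPM). Camera called both lists at the preset correlation (adjusted p = 3.50e-10 and 0.000476), and neither call held, at adjusted p = 0.602 with an estimated correlation for each. Levels of the matrix list were -0.60, -1.91 and -0.89 in PEGPH20 replicates 4, 5 and 6 relative to the vehicle mean, and without replicate 5 the medians of both lists were -0.79 and -0.69, with 16 and 5 genes past the threshold over all genes.

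Fibroblast genes were lower as well. The fibroblast list had 13 of 15 members lower (median -1.23), with 11 passing when adjusted over the list alone and 0 over all genes. It was led by Col3a1, the mesenchymal transcription factor Foxf1 (51.0 ± 0.84 against 22.3 ± 8.66 CPM, SD, n = 3 each) and Gpx3 (135 ± 9.58 against 54.3 ± 22.2 CPM). In the myofibroblast and TGF-beta list 16 of 18 were lower (median -1.02), with 4 passing when adjusted over the list alone and 0 over all genes. The leading members were Spon1 (94.2 ± 17.96 against 25.3 ± 14.9 CPM), Ltbp1, which binds latent TGF-beta (52.4 ± 3.76 against 24.9 ± 8.38 CPM), and Ccn4. All 14 measured genes of the inflammatory fibroblast list were lower (median -0.79) and 0 passed either way. They included Saa3, an acute phase protein (189 ± 86.0 against 34.7 ± 30.3 CPM), Grem1, a BMP antagonist (461 ± 133 against 204 ± 128 CPM), and complement C3. The epithelial-mesenchymal transition list had 16 of 16 lower (median -1.05), with 7 passing when adjusted over the list alone and 0 over all genes, among them Mmp2, Mmp3 and Cdh11. It shares 2 measured genes with the fibrillar matrix list and 2 with the fibroblast list, Mmp2 among the latter, so it is not a separate set. Camera called the 4 lists (adjusted p = 1.59e-05, 0.000838, 0.000838 and 6.43e-06), and all 4 calls were lost at adjusted p = 0.602 with an estimated correlation. Replicate 5 had the lowest level of each. Without it the 4 medians were -0.81, -0.50, -0.54 and -0.50, and 9 fibroblast genes passed over all genes.

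The level of the endothelial list was lower in all PEGPH20 libraries than in all vehicle libraries. All 15 measured endothelial markers were lower (median -0.82), and 11 passed when adjusted over the list alone, with 0 over all genes. Ptprb, an endothelial receptor phosphatase, was at 104 ± 3.09 CPM in vehicle and 43.8 ± 9.997 CPM in PEGPH20 tumors (SD, n = 3 each), Vwf at 11.8 ± 3.12 and 3.05 ± 0.91 CPM, and the VEGF receptor Kdr at 71.8 ± 9.78 and 40.3 ± 5.595 CPM. All 5 lymphatic endothelial markers were lower (median -0.77), and 2 passed when adjusted over the list alone, with 0 over all genes. These were Lyve1, a hyaluronan receptor, at 49.8 ± 0.96 and 23.1 ± 3.55 CPM, and the VEGF receptor Flt4 at 7.12 ± 0.21 and 2.53 ± 0.78 CPM. Pdpn was at 25.3 ± 7.33 and 14.7 ± 5.91 CPM. Camera called both lists (adjusted p = 9.17e-07 and 0.00401), with adjusted p = 0.602 with an estimated correlation for each. Endothelial levels in replicates 4, 5 and 6 were -0.53, -1.32 and -0.74 relative to the vehicle mean, and without replicate 5 the endothelial median was -0.57, with 4 genes past the threshold over all genes.

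Other stromal and non-epithelial markers were not called. Smooth muscle had a median of -0.40 (11 of 15 lower, adjusted p = 0.176), enteric glia and neuron -0.49 (8 of 9 lower, 0.0860), mesothelium -0.82 (3 of 3 lower, 0.201), adipocyte -0.37 (4 of 5 lower, 0.931) and erythroid and blood -0.45 (5 of 5 lower, 0.0894). Pancreatic acinar genes had a median of 0.25 over 4 measured members (adjusted p = 0.750). Adjusted over the list alone, Msln of the mesothelium list passed, and 0 genes of these lists passed over all genes. None of these lists was called without PEGPH20 replicate 5 either, and the medians were then -0.26 for smooth muscle, -0.34 for glia and neuron, -0.32 for mesothelium, -0.11 for adipocyte, -0.33 for erythroid and -0.28 for pancreatic acinar genes. Adjusted over the list alone, 2 glia and neuron, 2 mesothelium and 1 adipocyte gene were then lower. Over all genes 1 mesothelium and 1 adipocyte gene were lower.

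The hyaluronan list did not differ as a group. It had 9 measured members of 20, 3 higher and 6 lower, with a median of -0.13 (camera adjusted p = 0.948). Adjusted over the list alone, Ugdh, which makes the UDP-glucuronate used in hyaluronan synthesis, was higher (120 ± 10.9 against 181 ± 16.0 CPM, SD, n = 3 each) and Vcan, a hyaluronan-binding proteoglycan, was lower (70.5 ± 7.91 against 27.8 ± 12.5 CPM). Neither passed over all genes with all libraries, and both did without PEGPH20 replicate 5 (Ugdh log2 difference 0.61, adjusted p = 0.0309; Vcan -0.98, 0.00802). Itih5 was at 45.8 ± 3.89 and 37.4 ± 6.70 CPM.

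Of 10 lists of epithelial cell types, YAP/TEAD targets and proliferation, 5 were called by camera at the preset correlation and 0 with an estimated one. The YAP/TEAD list shares 2 measured genes with the myofibroblast and TGF-beta list, and its values in tumor tissue cannot be assigned to epithelium. Of the fetal-like and regenerative list 22 of 24 members were lower (median -1.38), with 0 passing adjusted over the list alone or over all genes. Msln was at 44.1 ± 13.7 CPM in vehicle and 8.17 ± 7.14 CPM in PEGPH20 tumors (SD, n = 3 each), Cldn4 at 145 ± 38.9 and 60.2 ± 37.97 CPM and Gja1 at 39.3 ± 7.97 and 20.7 ± 10.4 CPM. YAP/TEAD targets were lower in 20 of 22 (median -0.84), and adjusted over the list alone 6 were lower, among them Igfbp3 and Dlc1, and 1 higher, with 0 over all genes. Gadd45b was at 21.9 ± 3.07 and 13.2 ± 0.25 CPM. Enterocyte genes were higher in 26 of 29 (median 0.79), with Mep1b passing when adjusted over the list alone and 0 over all genes. The peptidase gene Dpp4 was at 51.8 ± 7.08 and 223 ± 214 CPM and Maf at 193 ± 7.34 and 543 ± 371 CPM. Paneth cell genes were higher in 11 of 13 (median 1.55), with the antimicrobial lectin Reg3g (690 ± 84.7 against 1374 ± 269 CPM) passing when adjusted over the list alone and 0 over all genes. Ang4 was at 3.67 ± 0.26 and 56.6 ± 74.0 CPM and Nupr1 at 35.1 ± 1.06 and 20.3 ± 6.88 CPM. Goblet genes were higher in 9 of 14 (median 0.15), with the secreted protease Clca1 (323 ± 51.2 against 609 ± 136 CPM) passing when adjusted over the list alone, beside Klk1 and the secretory lineage factor Atoh1, which did not.

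Camera called these 5 lists (adjusted p = 0.000838, 0.000542, 7.95e-08, 0.000603 and 0.0392), and none of the calls held. They had adjusted p = 0.632 with an estimated correlation for the fetal-like and goblet lists and 0.602 for the other 3. Much of the size came from PEGPH20 replicate 5, whose fetal-like level was -3.09 against -0.28 and -0.50 in replicates 4 and 6. Its enterocyte level was 2.17 against 0.23 and 0.28, and its Paneth level was 2.65 against 0.97 and 0.04. Vehicle levels ran from -0.46 to 0.53 for enterocyte and from -0.30 to 0.23 for Paneth genes, so the groups overlapped in both lists. Without it the medians were -0.36 for fetal-like, -0.49 for YAP/TEAD, 0.19 for enterocyte and 0.44 for Paneth genes, while more of their genes passed. Adjusted over the list alone, 12 fetal-like genes were then lower, 9 YAP/TEAD genes lower and 1 higher, 4 enterocyte genes higher and 1 lower, and 6 Paneth genes higher and 1 lower. Over all genes 2 fetal-like and 1 YAP/TEAD gene were lower, and 2 enterocyte genes, 1 Paneth gene and 1 goblet gene were higher. The goblet list was no longer called (adjusted p = 0.0504). The goblet call was also lost under TMM and RLE scaling. Stem cell and Wnt target genes (median -0.17, 14 of 20 lower, adjusted p = 0.616), proliferation genes (0.04, 19 of 30 higher, 0.256), enteroendocrine genes (0.27, 8 of 12 higher, 0.152), tuft cell genes (-0.03, 4 of 7 lower, 0.935, with a median above 0 under TMM, RLE and upper quartile scaling) and gastric-type genes (-0.14, 8 of 13 lower, 0.957) were not called. For the stem cell, tuft, macrophage and sex-linked lists the median was below 0 and camera's direction was up. Without replicate 5 the gastric-type median was 0.30 and that list and proliferation (0.14) were called higher, at adjusted p = 0.485 and 0.579 with an estimated correlation.

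**Figure D3:**
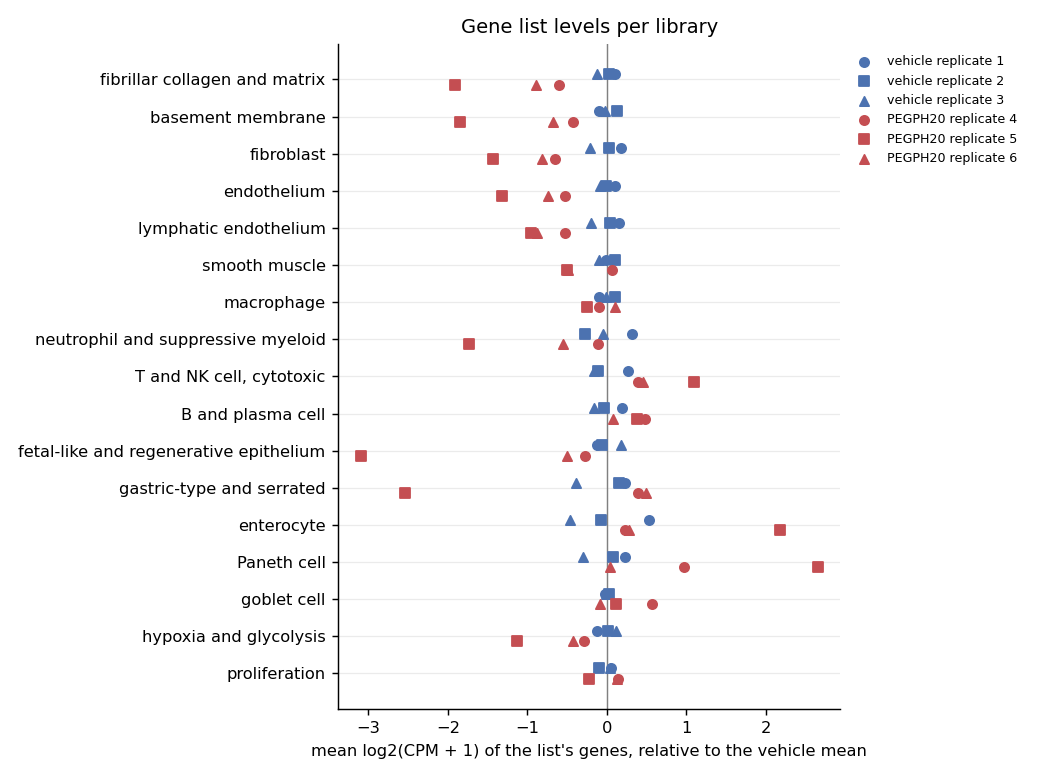
Levels of 17 gene lists per library, as the mean log2(CPM + 1) of each list's genes relative to the vehicle mean on the horizontal axis, with lists on the vertical axis; each point is a library. All 3 PEGPH20 libraries lie below the vehicle libraries for fibrillar matrix (-0.60, -1.91 and -0.89) and endothelium (-0.53, -1.32 and -0.74), and replicate 5 lies apart for enterocyte genes at 2.17.

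Of 8 immune lists 4 were called higher at the preset correlation and 0 with an estimated one, and 4 were not called in the main test. T and NK cell genes were higher in 5 of 6 measured members (median 0.89), with Cxcr6, a receptor of tissue-resident T cells (1.60 ± 0.55 against 5.02 ± 0.44 CPM, SD, n = 3 each), passing when adjusted over the list alone, with 0 over all genes. Trbc2 (7.32 ± 2.49 against 15.1 ± 5.02 CPM) and Ccl5 (10.5 ± 6.50 against 27.6 ± 30.3 CPM) did not pass. B and plasma cell genes were higher in 10 of 12 (median 0.36), and adjusted over the list alone 4 were higher and 1 was lower. The 4 included Jchain, the joining chain of secreted IgA and IgM (1804 ± 175 against 2963 ± 387 CPM), Iglc2 (54.4 ± 9.70 against 87.1 ± 2.26 CPM) and Mzb1. Interferon and MHC class I genes were higher in 23 of 32 (median 0.37). Irf1 was at 116 ± 5.20 and 191 ± 46.0 CPM and Mx1 at 2.75 ± 0.40 and 7.28 ± 1.60 CPM. In contrast Iigp1, an interferon-inducible GTPase, was lower (77.0 ± 19.3 against 35.3 ± 2.21 CPM) and the only member to pass adjusted over the list alone. All 10 MHC class II and dendritic cell genes were higher (median 0.49) and 0 passed adjusted over the list alone, with H2-Eb1 at 68.9 ± 3.68 and 129 ± 73.0 CPM and H2-Aa and H2-Ab1 also leading. Over all genes 0 members of these 4 lists passed.

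Camera called the T and NK, B and plasma, interferon and MHC class II lists (adjusted p = 0.0108, 0.00151, 0.000249 and 0.00700), with adjusted p = 0.602 with an estimated correlation for each. Without PEGPH20 replicate 5, the calls of the T and NK (median 0.34, adjusted p = 0.0985), interferon (0.14, 0.0964) and MHC class II lists (0.11, 0.420) were lost. Over all genes 1 B and plasma gene was then higher, and of the interferon list 1 gene was higher and 1 lower. Macrophage genes (median -0.03 and above 0 under TMM, RLE and upper quartile scaling, adjusted p = 0.935) were not called. Checkpoint and regulatory T cell genes (0.12 over 4 measured, 0.897), mast cell and eosinophil genes (-0.53, 4 of 5 lower, 0.185) and neutrophil genes (-0.73, 10 of 13 lower, 0.0606) were not called either. Adjusted over the list alone 4 neutrophil genes were lower, Mmp8, Ly6g, Arg1 and S100a8, and 0 passed over all genes. The list was called lower at the preset correlation under TMM, RLE and upper quartile scaling. Camera with an estimated correlation and no such scaling gave it an adjusted p of 0.632. Without replicate 5 the median of the neutrophil list was -0.004 (adjusted p = 0.420), with 2 genes lower over all genes.

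Hypoxia, p53, immediate early and mitochondrial lists were called by camera at the preset correlation and not with an estimated one. Hypoxia and glycolysis genes were lower in 22 of 25 (median -0.60), with 8 passing when adjusted over the list alone and 1, Ndrg1, over all genes. Bnip3 and the glycolytic enzyme gene Eno1 were next (Eno1 53.6 ± 5.31 against 26.4 ± 4.54 CPM, SD, n = 3 each). The p53 target and apoptosis list was lower in 15 of 21 (median -0.52), with 6 passing when adjusted over the list alone and 0 over all genes. They included Gdf15 (13.4 ± 2.03 against 3.68 ± 1.26 CPM), Pmaip1 (89.9 ± 4.57 against 53.1 ± 4.78 CPM) and the cell cycle inhibitor Cdkn1a (507 ± 18.1 against 359 ± 30.6 CPM). Immediate early and heat shock genes went both ways (median 0.18, 11 of 17 higher). Adjusted over the list alone Hsph1 was higher and Ier3 was lower (50.7 ± 5.35 against 20.8 ± 9.02 CPM), with 0 over all genes, and Dusp1 was at 34.8 ± 4.91 and 20.2 ± 12.7 CPM. All 7 measured mitochondrially encoded mRNAs were higher (median 0.22) with 0 passing adjusted over the list alone, such as mt-Cytb (4696 ± 638 against 6993 ± 1105 CPM), mt-Co1 and mt-Nd4. Camera called the 4 lists (adjusted p = 8.99e-05, 0.00754, 0.0380 and 0.00623), with adjusted p = 0.632 with an estimated correlation for the immediate early list and 0.602 for the others. Without replicate 5 the mitochondrial call was lost (median 0.11, adjusted p = 0.0504) and the hypoxia and p53 medians were -0.27 and -0.22, with 7 and 4 genes lower over all genes. The immediate early call was lost without vehicle replicate 1 or PEGPH20 replicate 4 or 6. Its median was 0.35 without PEGPH20 replicate 5 (adjusted p = 0.000121), with 3 genes higher and 1 lower over all genes. The sex-linked list had a median of -0.04 over 4 measured genes (adjusted p = 0.574) that was above 0 under TMM, RLE and upper quartile scaling, with Eif2s3y higher when adjusted over the list alone.

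In all, camera called 21 of 38 lists at the preset correlation, 9 higher and 12 lower, and 0 with an estimated correlation or by fry. Levels of the 2 groups did not overlap in 13 of the 21, the 12 lower lists and T and NK cells. They overlapped in the other 8 higher lists. Without PEGPH20 replicate 5 it called 18, of which 16 were among the 21, and again 0 with an estimated correlation. The median log2 difference of all genes was -0.09 and moved by 0.10 under RLE scaling, so list medians are relative to that level.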

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

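TMM scaling, edgeR on recovered reads, array weights, the prior count of 2, the pseudocounts for lists and the joint settings without PEGPH20 replicate 5 were added as alternatives after seeing the data. Of these, edgeR with TMM for counts and the prior count of 2 for lists were named in the design beforehand. The 9 genes (3 higher, 6 lower) became 10 under RLE, 9 under upper quartile and TMM scaling and 10 with edgeR, of which 8 were shared. DESeq2 called 272 (135 higher, 137 lower), limma-voom 18 (5 and 13), limma-voom with sample quality weights 269 (108 and 161), array weights 871 (294 and 577), and no filter 29 (10 and 19). A pseudocount of 0.1 gave 3 lower genes. Leaving out a library gave 1 to 339 genes, 1 to 108 higher and 0 to 231 lower. The upper end was without PEGPH20 replicate 5, where edgeR called 421 (173 and 248), 330 of them among the 339. The array weight of that library was 0.193. The 9 genes kept their direction in every alternative run, and Ubb also stayed past the threshold. Fmo2 missed it under RLE (adjusted p = 0.0587), TMM and upper quartile scaling, with edgeR and with the pseudocount of 0.1; Wif1 and Pi15 missed it with that pseudocount. The causes were not tested.

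The 21 lists called became 18 to 24 when a library was left out, 21 or 22 under the scalings and 24 with no filter. With an estimated correlation or fry there were 0, and with an estimated correlation also 0 without PEGPH20 replicate 5. The estimated correlation was 0.116 to 0.817 in 20 of the 21 lists, which widens the error of a list's mean by construction. For T and NK cells it was 0.009, under the preset 0.01, so the size of the correlation does not account for that lost call. Their unadjusted camera p went from 0.00541 with the preset to 0.0495 with the estimate. With an estimated correlation camera takes its degrees of freedom from the few libraries and not from the genes, which lowers its power. A call lost there does not show that a list is unchanged. Fry's test for change in either direction passed for 7 lists: lymphatic endothelium (adjusted p = 0.00669), B and plasma (0.0308), p53 (0.0308), T and NK (0.0374), and endothelium, hypoxia and immediate early (0.0455 each). Medians changed sign for lists that were not called, and outside the scalings the cause was not tested. Without PEGPH20 replicate 5, with either correlation, they were hyaluronan 0.053, checkpoint -0.072, stem cell 0.093, enteroendocrine -0.164, tuft 0.016, gastric-type 0.301 and pancreatic acinar -0.280. Under RLE, upper quartile and TMM scaling and prior counts of 0.5 and 2, macrophage was 0.064, 0.027, 0.052, 0.062 and 0.053, tuft 0.058, 0.020, 0.046, 0.043 and 0.045, and sex-linked 0.060, 0.017, 0.046, 0.046 and 0.045. RLE, upper quartile and TMM scaling moved the median of all genes by 0.101, 0.059 and 0.087. That is more than the unscaled medians of macrophage (-0.026), tuft (-0.033) and sex-linked genes (-0.044) lay below 0. Gastric-type was 0.072 with a pseudocount of 5. Over the left-out libraries the range was -0.296 to 0.053 for hyaluronan, -0.072 to 0.284 for checkpoint, -0.223 to 0.049 for macrophage, -0.294 to 0.093 for stem cell, -0.164 to 0.534 for enteroendocrine, -0.207 to 0.260 for tuft, -1.076 to 0.301 for gastric-type, -0.045 to 0.137 for proliferation and -0.280 to 0.574 for pancreatic acinar. For Prkci it was -0.0049 to 0.3919. Depth limits genes near 1 CPM: 1 read is 0.353 to 0.482 CPM, so the hyaluronan synthases could not be compared.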

Other observations

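The genes in the paragraphs on immunoglobulins, mitochondrial tRNAs and clock genes (there all but 5 named as not looked at before) were chosen after their values were seen, as were all tests here except those of the pseudogene sum and of the region around Ubb, which were written before their results. For PEGPH20 replicate 5 as an outlier, 2 further tests were run and are not set out further, since 3 patterns are weighed here at most: its read total lay between those of the other PEGPH20 libraries, and most genes called without it lay on the PEGPH20 side in it.

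Of the tested heavy chain and kappa constant genes looked at here, 3 IgG genes had lower means in PEGPH20 tumors and 3 others had higher means, with no test between classes. The lambda constant genes Iglc1 (327 against 388 CPM) and Iglc2 (54.4 against 87.1 CPM) also had higher means. Ighg1 was at 164 ± 28.5 CPM in vehicle and 32.9 ± 17.5 CPM in PEGPH20 tumors (SD, n = 3 each; log2 difference -2.45, limma adjusted p = 0.0979), Ighg2c at 168 ± 23.7 and 30.3 ± 19.1 CPM (-2.68, 0.115) and Ighg2b at 186 ± 19.3 and 90.7 ± 26.6 CPM (-1.07, 0.143). The IgA gene Igha was at 7700 ± 2609 and 8823 ± 838 CPM (0.25, 0.626), Ighm at 2.08 ± 1.18 and 5.98 ± 1.07 CPM (1.26, 0.177), Igkc at 5328 ± 1335 and 6545 ± 917 CPM (0.32, 0.461) and Pigr, the receptor that carries IgA across epithelium, at 238 ± 95.6 and 1416 ± 739 CPM (2.54, 0.0905). None passed with all libraries. Without PEGPH20 replicate 5 the differences were -1.91, -2.05 and -0.80 for Ighg1, Ighg2c and Ighg2b and 2.14 for Pigr, all past the threshold (adjusted p = 0.000369, 0.000395, 0.00858 and 0.00441). Near-identical constant regions can share reads, so the split between IgG subclasses is uncertain.

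Transfer RNAs of the mitochondrial genome summed to 251, 242 and 255 CPM in vehicle and 499, 688 and 420 CPM in PEGPH20 libraries.

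The lower matrix, fibroblast and endothelial lists may reflect stroma in these tumors, the tissue piece of replicate 5, or both. Replicate 5 alone does not account for them, since replicates 4 and 6 were low too. Together these 2 lay -0.74 from vehicle on the matrix list, where the vehicle SD was 0.12, and both were below every vehicle library. Both were also below every vehicle library on the fibroblast list (-0.65 and -0.81) and the endothelial list (-0.53 and -0.74). This check was written after these levels were seen and describes these libraries only. For an equal loss of all non-epithelial cells, a comparison was made with all 12 fixed lists of non-epithelial cell types outside fibroblasts and vessels. The mean of the matrix, fibroblast and endothelial levels minus the mean of these 12 differed by -0.74 (SE 0.19) without overlap between groups. The matrix, fibroblast and endothelial lists were picked after they were seen to be low, which favors such a difference. The comparison therefore cannot decide on an equal loss. The 12 levels went apart, from T and NK cells (0.65, SE 0.26) and macrophages (-0.08, SE 0.12) to glia (-0.56), mast cells (-0.67) and mesothelium (-1.29), so a loss of some of these cell types stays open. More normal mucosa in replicate 5 stays open for the size of its values: its enterocyte level was 1.92 above the mean of replicates 4 and 6 and its Paneth and enteroendocrine levels were also above both, but goblet and tuft levels were not, and no normal mucosa library was analysed here. An effect of treatment on stroma, which the design names, was not tested and stays open.

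Ubb was at 1.45, 1.91 and 4.59 CPM in vehicle libraries, and at 233, 250 and 194 CPM in PEGPH20 libraries. Other settings for shared reads in 1 group would likely move processed pseudogenes as a class, and their summed level over 1437 genes had a ratio of 0.892 (SE 0.032, PEGPH20 over vehicle), inside the bounds set beforehand although the groups did not overlap. A strain segment that changes many genes around Ubb is argued against by the 83 other genes tested within 5 Mb. Of these, 9 passed an unadjusted p under 0.05, an odds ratio of 0.552 (95% interval 0.243 to 1.11, Fisher's exact p = 0.113). A segment that changes few genes or Ubb alone would go unseen in this test and stays open. Shared reads of Ubb itself were not analysed here and stay open. Another 3' end of its transcript and an effect of treatment were not tested.

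Some clock output genes were lower, with Tef at 39.2 ± 3.08 and 13.5 ± 3.94 CPM, Per3 at 18.7 ± 1.73 and 4.69 ± 2.29 CPM and Per1 at 16.0 ± 1.41 and 6.29 ± 1.249 CPM (SD, n = 3 each). Others were not lower in the mean, such as Nr1d1 at 12.3 ± 0.72 and 12.97 ± 7.58 CPM and Usp2 at 10.3 ± 2.51 and 12.3 ± 10.7 CPM. Both of these means rest on replicate 5. Replicates 4, 5 and 6 had 11.3, 21.3 and 6.37 CPM of Nr1d1 and 6.71, 24.6 and 5.46 CPM of Usp2. Replicates 4 and 6 thus lay below every vehicle library for both genes. Bhlhe41, too low to test, also had a higher mean (2.24 against 3.42 CPM). By limma none was past the threshold with all libraries, and 4 of the 13 tested clock genes were past it without replicate 5. Collection at another time of day is a candidate explanation: genes of the opposite phase minus evening output genes differed by 1.34 (SE 0.21) without overlap. For the 5 genes not looked at before (Hlf, Bhlhe41, Usp2, Clock and Nfil3) the difference was 0.65 (SE 0.38) with overlap. The overlap came from replicate 5, at 2.67 against 3.64 and 2.93 in replicates 4 and 6, with vehicle libraries at up to 2.87. The explanation stays open, since that overlap is there with all libraries and the collection time is not in the labels used here. A warmer tissue is another: heat-induced minus cold-induced genes (Cirbp and Rbm3) differed by 1.81 (SE 0.19), but heat-induced genes alone differed by 0.49 (SE 0.27) with overlap, and replicate 5 had 12.5 CPM of Hspa1b within the vehicle range. Time, temperature and treatment cannot be told apart here.

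With 10 splits of the 6 libraries into groups of 3, no share under 0.05 can be reached. The real split gave 9 genes and was the 1 split with as many, the highest of the others giving 0. For lists 2 of the 10 splits gave 21 or more, the real one with 21 and the highest other also with 21, which set vehicle replicates 1 and 3 with PEGPH20 replicate 4. Splits that mixed the groups gave 9 to 21 lists at the preset correlation. The number of lists called therefore does not set the treatment grouping apart.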
